A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

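Total RNA of 4 yeast cultures was hybridised to Affymetrix yeast genome arrays, 1 array for each of nab3-11 at 37 °C, nab3-11 at 25 °C, wild type at 25 °C and wild type at 37 °C. Per the labels' protocols, cells grew in YPD and were kept for 2 hours at the stated temperature, RNA was extracted with hot acid phenol and cleaned on columns, and biotin-labelled RNA was made after 1 round of amplification with an oligo(dT) primer carrying a T7 promoter. Such priming favours polyadenylated RNA, so signals of snoRNAs, tRNAs and rRNA depend on how they are primed. The deposited values are the authors' probe-set intensity on a linear scale, made with MAS5 in GCOS 1.1.1 per the submitters' processing notes. From the values, each array had been scaled by the authors to a trimmed mean near 150, which hides any change in total RNA per cell. Detection calls were not used here.

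Each array was rescaled to the same 2% trimmed mean of 150. Values below the floor of 21.8, the 40th percentile of scaled signal over all non-control probe sets and arrays, were raised to it before log2 was taken. A gene was measured in a comparison when its highest signal there lay above the floor, and a fold against a value below the floor is a lower bound, written "at least". Differences between such values understate low genes. Genes were called at 2-fold, a log2 difference of 1. There is 1 array per group, so no test, standard error or p-value was computed, and no additive fit was made, because it would use the comparison of interest as its error.

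Of the 9335 probe sets, 60 were controls, 6504 had exactly 1 gene in the platform annotation, 328 had several and 2443 non-control probe sets had none. All 6504 were matched by gene ID to the R64 annotation, which gave current names and neighbouring genes only; the build of the array design is not given in the sources used here, so no coordinates are printed. For the 315 genes with more than 1 probe set, the brightest was used. Where several measured probe sets of a gene existed (156 genes), their log2 differences between mutant and wild type at 37 °C spanned a median of 0.32, with a 90th percentile of 0.95. Probe sets with several genes or none were kept out of gene counts.

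The 6 comparisons were mutant against wild type at each temperature, 37 °C against 25 °C in each strain, the strain-by-temperature difference, and the mutant at 37 °C against both controls. The last set needs at least 2-fold the same way against wild type at 37 °C, against the mutant at 25 °C and in the strain-by-temperature difference. Named genes followed a fixed rule: NAB3, NRD1 and IMD2 throughout; the 15 highest and 10 lowest genes against both controls by the smaller difference; at 37 °C the 10 highest and 10 lowest differences between mutant and wild type with both signals above the floor, and the 5 highest bounds; in each other pairwise comparison the 5 highest and 5 lowest; and up to 4 genes of each list by the size of their difference. In all, 35 gene lists were fixed, from RNA processing, stress, growth, cell cycle, mating type and nutrient regulons. Each list median was set against 10000 random lists of the same size matched on mean signal, as a description of these arrays. Genes downstream of snoRNAs were the next protein-coding genes on the same strand within 1000 bp. The groups, comparisons, lists, naming rule, floor and 9 alternatives were chosen before the data were examined.

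The alternatives were the values as deposited, scaling to a common median, quantile normalization, a floor at the 25th or 55th percentile, a floor that is added instead, the mean over probe sets, unique probe sets only and a 3-fold threshold. An alternative without the wild type 37 °C array was chosen after seeing the data, because its description conflicts with its other labels; the description of the wild type 25 °C array does so too. Without replicates, a count or value is called moved when it changes more than 1.5-fold. The calls were tested on simulated data built from these arrays: for mutant against wild type at 37 °C over 5656 genes, 84% of genes changed 2.5-fold and 98% of genes changed 4-fold were recovered, and 59% and 93% in the set against both controls. Of 5456 unchanged genes, 55 (1.01%) were called, and 12 in that set. These shares depend on the noise put into the simulation and do not measure the variation of the 37 °C arrays, which have no replicates. Overlap of comparisons that share the mutant 37 °C array was set against 100 simulated draws with no effect, with noise taken from the strain difference at 25 °C. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.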

Results

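RNA of budding yeast was measured on 4 whole-genome expression arrays, 1 for each combination of strain and temperature. The mutant strain carried nab3-11, a temperature-sensitive allele of NAB3, and the control was a wild type strain. Nab3 is an RNA-binding protein that acts with Nrd1 and the helicase Sen1 to end transcription of snoRNAs and other short, non-coding transcripts. Both strains were grown in rich medium and kept for 2 hours at 25 °C or at 37 °C, the temperature at which the allele is inactivated. Each array reported 9335 probe sets, of which 6504 belonged to exactly 1 gene and gave values for 5656 genes. Between 56.5% and 64.4% of non-control probe sets lay above the floor of 21.8 signal units on each array. There are no replicates, so every difference below compares single arrays, carries no error or p-value, and has a precision limited by the number of arrays. A gene is called higher or lower when its signals differ at least 2-fold.

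The transcript of the mutated gene itself differed little between the arrays. NAB3 signal was 81.1 in the mutant at 37 °C, 72.2 in the mutant at 25 °C, 66.3 in wild type at 25 °C and 66.8 in wild type at 37 °C. The allele is not a deletion, so this probe set does not check the strain labels. A control probe set for URA3 separated the strains at both temperatures, with signals of 74.5 and 76.1 on the mutant arrays at 37 °C and 25 °C against 165 and 168 on the wild type arrays, whereas the probe set of the gene itself had 48.2 and 81.5 against 97.8 and 96.5. NRD1, which encodes the partner of Nab3 and whose own transcript is subject to early termination by this pathway, had a signal of 717 in the mutant at 37 °C, 291 in the mutant at 25 °C, 125 in wild type at 25 °C and 88.9 in wild type at 37 °C. It was thus 8.06-fold higher in the mutant than in wild type at 37 °C and already 2.32-fold higher at 25 °C. IMD2, an IMP dehydrogenase gene regulated by early termination, had signals of 1174 and 572 in mutant and wild type at 37 °C and of 1373 and 1233 at 25 °C. Between 25 °C and 37 °C it was 2.16-fold lower in wild type and 1.17-fold lower in the mutant. Single arrays do not assign its 2.05-fold difference at 37 °C to either strain. Its probe set can also bind related genes. A label conflict bears on every comparison that uses a wild type array: the descriptions of both wild type arrays name the mutant at 25 °C, whereas their titles and strain entries name wild type, at 25 °C and at 37 °C, and the titles were followed.

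The main question of the design is which transcripts differ when Nab3 is inactivated, beyond the effects of temperature and of strain. In the mutant at 37 °C, 132 genes were higher than in both the mutant at 25 °C and wild type at 37 °C, and in the strain-by-temperature difference. Small nuclear and nucleolar RNAs were well represented among them: 21 were snoRNA genes, 2 were snRNA genes and 9 were tRNA genes, and the other 100 were protein-coding. The snoRNA SNR128 had a signal of 1967 in the mutant at 37 °C and of 116, 107 and 99.91 in the mutant at 25 °C, wild type at 25 °C and wild type at 37 °C. SNR9 was 12.3-fold higher than in wild type at 37 °C and 8.44-fold higher than in the mutant at 25 °C. SNR3 and SNR56 were at least 20.7-fold and at least 19.1-fold higher than in wild type at 37 °C, where both lay below the floor. SNR45 was 8.74-fold higher than in wild type, and the spliceosomal RNAs SNR14 and SNR7-L were at least 7.87-fold and at least 13.0-fold higher.

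Among the 15 highest genes of this set by their smaller difference, 8 were protein-coding. ULI1 was 19.3-fold and the cell-surface protein gene ZPS1 8.79-fold higher than in wild type at 37 °C. GRE1, a stress-induced hydrophilin gene, was at least 12-fold higher and GAT4, a GATA-type transcription factor gene, at least 8.88-fold higher. The remaining members of the 15 were short reading frames: YKL183C-A was at least 13.6-fold higher, YHR214C-D 14.7-fold, YCR108C 7.77-fold and YJL136W-A at least 7.03-fold. The probe sets for SNR7-L, YCR108C and YJL136W-A can bind further sequences or use an incomplete probe set, by their type. Probe sets of such types were also used for RPL9A, SNR39B, CRG1 and the tRNA gene SUP19, named below.

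In the mutant at 37 °C, 54 genes were lower than on both control arrays and in the strain-by-temperature difference. All 54 were protein-coding, as were 4680 of the 4811 measured genes. NOP13 and NOP15, which encode nucleolar proteins, had log2 differences of -2.39 and -1.79 to wild type at 37 °C, with signals of 32.1 and 59.7 against 168 and 207. HMS2, a gene for a protein related to heat shock factors, was 4.09-fold lower, TAF10, a gene for a subunit of TFIID and SAGA, 4.15-fold lower, and VMA8, a vacuolar ATPase subunit gene, 3.41-fold lower. The cell separation glucanase gene DSE4 was 3.78-fold lower, the cell cycle inhibitor gene FAR1 2.72-fold, the vacuolar transporter gene VBA4 2.72-fold and the ribosomal protein gene RPL9A 2.66-fold lower. GYP7, which encodes a GTPase-activating protein of vesicle transport, had a signal of 30.3 in the mutant at 37 °C, 113 in the mutant at 25 °C, 83.5 in wild type at 25 °C and 296 in wild type at 37 °C.

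Both of these comparisons use the mutant 37 °C array, so part of their overlap arises without any effect. Ignoring the strain-by-temperature condition, 180 genes were higher and 64 lower in both. Simulated arrays with no effect gave means of 12.5 and 6.41 such genes, and independent lists of the observed sizes would share 34.5 and 7.35. Across 4811 genes, which are not independent replicates, the differences correlated with r = 0.65 against 0.50 in the simulation, with a covariance of 0.331 against 0.0719. The simulated noise came from the strain difference at 25 °C. A simulated comparison called means of 39.95 higher and 40.56 lower genes, against 228 and 188 observed between mutant and wild type at 37 °C. The simulated overlap and covariance therefore do not measure what the shared array contributes. Part of the excess may come from the shared array. With scaling to a common median the split of the set moved from 132 higher and 54 lower to 107 and 84, of which 107 and 52 were shared with the original set, and with quantile normalization it was 116 and 100. Leaving out the wild type 37 °C array, a comparison chosen after seeing the data that keeps the temperature effect, 616 genes were higher and 134 lower than on both 25 °C arrays, among them 30 of 47 snoRNA and snRNA genes. The wild type 25 °C array in that comparison has the same label conflict.

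**Figure D1:**
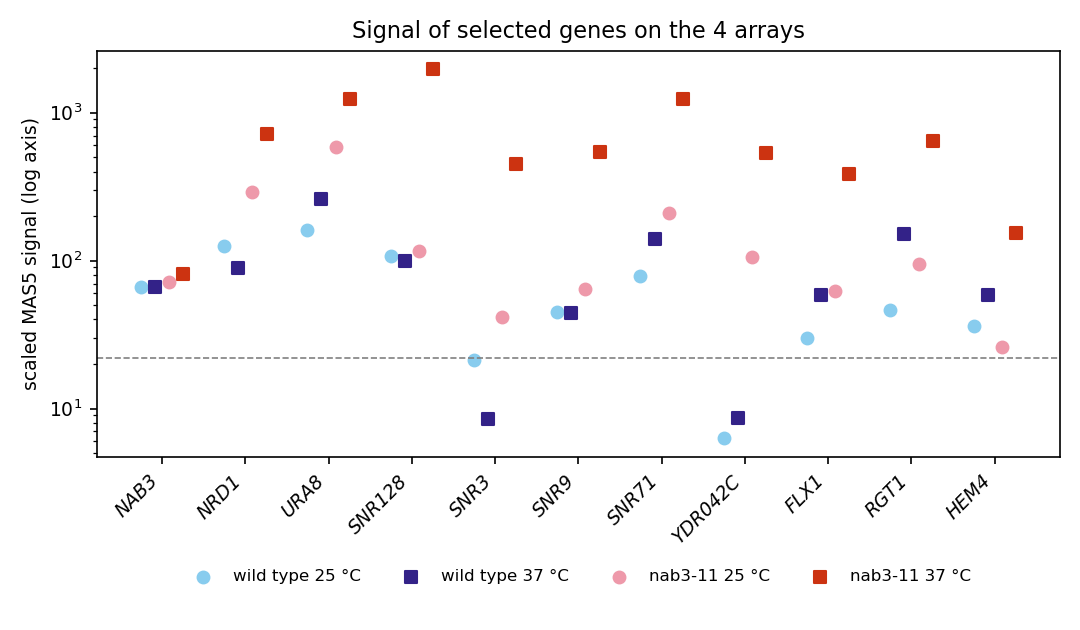
Scaled MAS5 signal (log axis) of 11 genes on the 4 arrays, with 1 point per array and the floor of 21.8 as a dashed line. NAB3 lies between 66.3 and 81.1 on all arrays, whereas SNR128 is at 1967 in the mutant at 37 °C and between 99.91 and 116 on the other arrays.

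At 37 °C the mutant differed from wild type in 416 of 4770 measured genes, 228 higher and 188 lower. The snoRNA and snRNA list was higher as a group: 30 of its 47 measured genes were at least 2-fold higher and 0 were lower, with a median log2 difference of 1.43, above 100% of 10000 random lists of matched size and signal. On the same array, tRNA genes, a list chosen after seeing the data, were higher for 31 of 71 with a median of 0.83, and a control probe set for the 25S rRNA was 6.44-fold higher. SNR71 was 8.81-fold higher and SNR39B 7.38-fold higher. The largest lower bound of all genes was that of YDR042C, which lies downstream of the snoRNA gene SNR47 and was at least 24.4-fold higher, with a signal of 532 against 8.60. Of the other protein-coding genes next downstream of an snoRNA or snRNA gene in the R64 annotation, FLX1, a mitochondrial carrier gene, was 6.58-fold higher, the glucose-responsive transcription factor gene RGT1 4.25-fold, the heme synthesis gene HEM4 2.61-fold and the tRNA splicing gene SEN2 2.45-fold. This list as a whole had 5 higher, 2 lower and 23 other genes among 30, and its median was 0.17, at percentile 98.1. In the strain-by-temperature difference its median was 0.04 at percentile 76.1, and for the mutant at 37 °C against 25 °C 0.21 at percentile 62.1. Of a hand-picked list of such genes, 1 of 4 was higher.

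Among the 7 genes taken to be controlled by Nrd1 and Nab3, 3 were higher and 0 lower, with a median of 0.49 at percentile 99.8. They were NRD1, URA8 (a CTP synthase gene, 4.76-fold) and IMD2, while HRP1 differed by 0.49 on the log2 scale. In the strain-by-temperature difference this list had 1 higher gene, NRD1, and 1 lower, GSC2 (-1.67), with a median of 0.39 at percentile 96.5. URA8 was already 3.63-fold higher at 25 °C. IMD2 signal in the mutant was 1174 at 37 °C and 1373 at 25 °C. Genes of the PAU and COS families, multicopy families near chromosome ends, were higher for 10 of 16 measured members, with a median of 1.17 above 100% of the random lists. PAU13 was 3.50-fold, PAU10 2.78-fold, PAU4 2.71-fold and PAU16 2.60-fold higher. Probe sets of these families can bind several members, and with unique probe sets alone the median was 0.31.

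Several growth-related lists lay lower in the mutant at 37 °C, mostly by less than 2-fold per gene. Ribosome biogenesis genes had a median of -0.56, below all random lists (percentile 0), with 2 of 44 genes passing the threshold, DBP3 and UTP22, each 2.26-fold lower. Cytosolic ribosomal protein genes, listed by a name pattern, had a median of -0.40 at percentile 0. In this list 4 of 81 were lower: RPL9A, RPL9B (2.22-fold), RPS26B (2.05-fold) and RPP1 (2.28-fold). RPP1 encodes an RNase P subunit, not a ribosomal protein, and is listed only because its name matches the pattern. This list was also lower in the mutant at 25 °C, with a median of -0.32 at percentile 0 and 76 of 81 genes below zero, and its strain-by-temperature median was -0.08. M/G1 genes had a median of -0.79 at percentile 0, and DSE4, ASH1 (2.74-fold) and EGT2 (2.01-fold) were the 3 lower genes of 10. The G2/M list had a median of -0.46 without any gene past 2-fold among 10, and the G1/S list one of -0.02, with YOX1 2.36-fold higher.

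Of the machinery around Nab3, few genes differed at 37 °C. RRP6, the nuclear exosome exonuclease gene, was 2.05-fold lower than in wild type and 2.60-fold lower than in the mutant at 25 °C. The list of Nrd1, Nab3, Sen1 and TRAMP factors had NRD1 higher and RRP6 lower among 10 genes. The exosome list, which also holds RRP6, had this gene as its 1 lower of 11 and a median of -0.34. Of the cleavage and polyadenylation factor genes, 0 of 17 passed the threshold. Besides those named, the highest and lowest genes by size among those with both signals above the floor were ULI1, YHR214C-D and ZPS1 on the one side, and OTU1 (5.83-fold lower), FMP41 (3.99-fold), YBR053C (3.86-fold), the NAD synthesis gene BNA6 (3.62-fold) and the transcription factor gene SOK2 (3.50-fold) on the other. In simulated data, a 2.5-fold change was recovered for 84% of genes and a 4-fold change for 98%, while 55 of 5456 unchanged genes passed the threshold. These shares rest on the simulated noise, as the 37 °C arrays have no replicates.

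**Figure D2:**
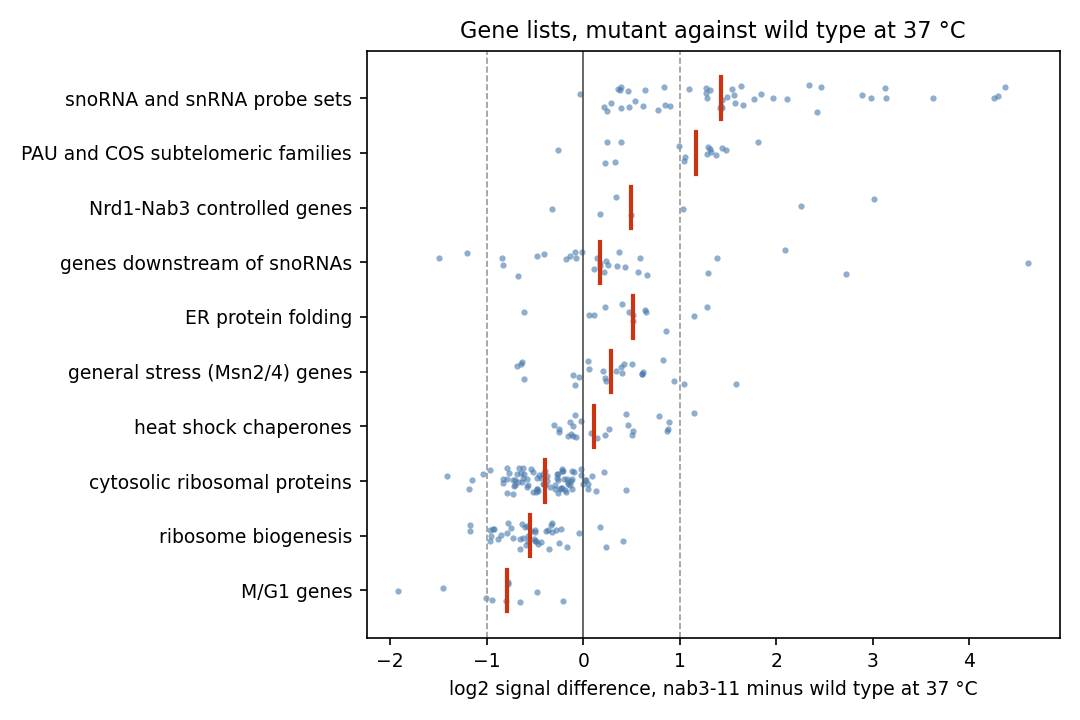
Log2 signal difference between nab3-11 and wild type at 37 °C for the measured genes of 10 lists, with 1 point per gene, the list median as a red bar and the 2-fold thresholds as dashed lines. The snoRNA and snRNA list has a median of 1.43, and the M/G1 list one of -0.79.

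In wild type, the shift to 37 °C was marked by stress genes. General stress genes controlled by Msn2 and Msn4 were higher for 17 of 22 measured members, with a median of 1.77. HSP12, a small membrane-stabilising heat shock protein gene, was 63.4-fold higher, the glycogen phosphorylase gene GPH1 at least 14.9-fold and TFS1 9.14-fold. YRO2 was 12.8-fold, PUG1 9.54-fold and CRG1 8.20-fold higher. Of the heat shock chaperones 8 of 23 were higher and 1 lower, among them HSP26 (at least 14.1-fold), SSA4 (6.78-fold) and SSE2 (3.97-fold), whereas the list median of 0.03 changed sign between scalings. Cell wall integrity genes were higher for 8 of 25 members with a median of 0.72, including GSC2, an alternate glucan synthase subunit gene, at 7.69-fold and PIR3 at 7.33-fold.

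The genes of the α mating type were among the lowest at 37 °C in wild type. All 4 MATα-specific genes were at least 2-fold lower, and MF(ALPHA)2, a pheromone gene, had a signal of 2440 at 25 °C and 46.3 at 37 °C, a 52.7-fold difference, and the agglutinin gene SAG1 was 21.0-fold lower. The phosphate transporter gene PHO89 was 18.0-fold lower, the iron uptake oxidase gene FET3 9.96-fold and the reductase gene FRE4 5.58-fold. Amino acid synthesis genes had a median of -0.78 with 12 of 33 lower, the phosphate list one of -0.70 with 4 of 11 lower, and the iron list one of -0.59 with 4 of 12 lower. Cytosolic ribosomal protein genes had a median of -0.49 with 0 of 81 past the threshold.

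In total 514 of 4650 genes were higher and 67 lower in wild type at 37 °C. NAB3, NRD1 and IMD2 had log2 differences of 0.01, -0.50 and -1.11. The split depended on scaling: 88.5% of the called genes were higher with the trimmed-mean scale, 52.6% with a common median and 64.6% with quantile normalization. The median of all genes moved from 0.29 to -0.03 and -0.02, so the values above are read against a median of 0.29.

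In the mutant, stress genes and snoRNA genes were both higher at 37 °C. General stress genes were higher for 16 of 24 members with a median of 1.71, with HSP12 29.1-fold, DDR2 12.5-fold and SOL4 10-fold higher. Heat shock chaperones were higher for 10 of 24 members with a median of 0.67, above all random lists, where wild type had 0.03 at percentile 59.5, and HSP26 was at least 25.7-fold and SSA4 12.5-fold higher. The snoRNA and snRNA list had 30 of 47 genes higher and a median of 1.65, where wild type had 6 of 34 and 0.50. SNR128 was 16.9-fold higher, SNR45 at least 16.6-fold, and the protein-coding genes CPP3 and ULI1 13.9-fold and 13.2-fold. PAU and COS genes were higher for 11 of 16 members, and 2 of 16 in wild type.

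All 4 MATα-specific genes were lower in the mutant too, with MF(ALPHA)2 31.1-fold and SAG1 4.8-fold lower. PHO89 was 10.4-fold, FET3 10.1-fold, the siderophore transporter gene SIT1 7.04-fold and FAR1 6.63-fold lower. Amino acid synthesis genes had a median of -1.0 with 16 of 32 lower, and the phosphate list one of -1.46 with 7 of 11 lower. The iron list had 5 of 13 lower, but its median was only -0.03, at percentile 13.0. Ribosome biogenesis genes had a median of -0.54 with 9 of 45 lower, and M/G1 genes one of -1.11 with 6 of 10 lower.

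In total 727 of 4630 genes were higher and 188 lower in the mutant at 37 °C than at 25 °C, and NAB3, NRD1 and IMD2 had log2 differences of 0.17, 1.30 and -0.23. Of the called genes 79.5% were higher with the trimmed-mean scale, 48.7% with a common median and 52.1% with quantile normalization, and the median of all genes moved from 0.21 to -0.10 and -0.08. The temperature differences of the strains share no array. They correlated across 4811 genes with r = 0.63 and a Spearman coefficient of 0.58, with 321 genes higher in both strains against 77.7 for independent lists and 37 lower in both against 2.62.

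**Figure D3:**
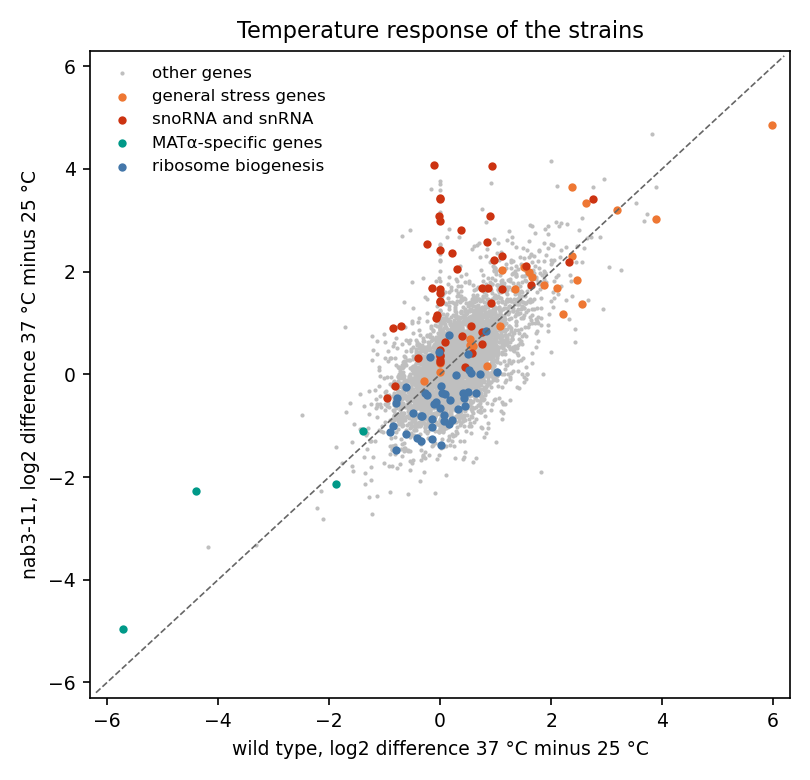
Log2 signal difference between 37 °C and 25 °C in wild type (horizontal) and nab3-11 (vertical), with 1 point per measured gene, 4 lists in colour and a dashed line where the strains are equal. Points are genes above the floor on at least 1 array. The correlation across genes is 0.63. The snoRNA and snRNA genes have medians of 0.50 over the 34 measured in the wild type comparison and 1.65 over the 47 measured in that of the mutant.

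At 25 °C, where the allele is permissive, the strains were close: 50 of 4282 genes were higher and 23 lower in the mutant. GSC2 was 4.04-fold higher, URA8 3.63-fold, the glycerophosphoinositol transporter gene GIT1 3.60-fold, the methyltransferase gene RKM5 3.34-fold and the SNARE gene SFT1 3.34-fold. GSC2, also called FKS2, URA8 and NRD1 were the 3 higher genes of the 7 in the Nrd1 and Nab3 list, and NAB3 and IMD2 differed by 0.12 and 0.15 on the log2 scale. The snoRNA and snRNA list had a median of 0.28, above all random lists, with 5 of 36 higher, among them SNR71 (2.66-fold) and SNR54 (at least 3.45-fold). By lists added after the data were seen, 3 of the 4 inside protein-coding genes were higher, with a median of 1.04. Of those outside, 2 of 32 were higher, with a median of 0.21. YDR042C was at least 4.82-fold higher. ER protein folding genes had a median of 0.55, above all random lists, with 0 of 13 past 2-fold.

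The lowest genes in the mutant at 25 °C were the vacuolar aminopeptidase gene APE1 (2.78-fold lower, and at least 8.92-fold at 37 °C), SUP19 (2.71-fold), YCL049C (2.69-fold), ZIM17 (2.64-fold) and SMN1 (2.46-fold). The share of called genes that were higher was 68.5% with the trimmed-mean scale, 58.5% with a common median and 56.9% with quantile normalization. The strain differences at 25 °C and at 37 °C, which share no array, correlated with r = 0.20 across genes, and 21 genes were higher at both temperatures against 2.37 for independent lists.

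The strain-by-temperature difference, the temperature difference of the mutant minus that of wild type, was at least 2-fold for 215 genes in the positive and 262 in the negative direction of 4811. For snoRNA and snRNA genes its median was 1.18 with 24 of 47 higher and 0 lower, for PAU and COS genes 1.25 with 11 of 16 higher and 1 lower (a median of 0.00 with unique probe sets alone), for ribosome biogenesis genes -0.53 with 5 of 45 lower, and for M/G1 genes -0.88 with 3 of 10 lower. General stress genes had a median of 0.02 with 1 of 24 higher and 3 lower. Heat shock chaperones had a median of 0.41 at percentile 99.96, with 18 of 24 above zero and 0 past the threshold. NAB3, NRD1 and IMD2 had values of 0.16, 1.80 and 0.88.

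The other lists are summarised for mutant against wild type at 37 °C. ER protein folding genes had a median of 0.52 with 2 of 13 higher, SIL1 (2.43-fold) and DER1 (2.22-fold). The iron list had 3 of 13 higher, HMX1, ARN1 and TIS11, and the phosphate list 2 of 11 lower, PHO5 and SPL2. Among amino acid synthesis genes MET6 and HIS1 were the 2 lower of 32. General stress genes had a median of 0.29 with DDR2 (3.0-fold) and GSY2 the 2 higher of 24, and heat shock chaperones 0.11 with BTN2 the 1 higher of 24. Of the purine list IMD2 was higher and ADE13 lower, of the pyrimidine list URA8 higher and URA3 lower, and of the marker genes TRP1 higher and URA3 and HIS7 lower. SAG1 was 5.01-fold higher as 1 of 4 MATα-specific genes, FAR1 the 1 lower of 8 haploid-specific genes, and REC104 (at least 5.52-fold higher) and IME1 (at least 2.35-fold lower) stood out among 5 measured meiosis genes. None of the measured genes passed the threshold in the lists for oxidative phosphorylation (0 of 32), glycolysis (0 of 15), cell wall integrity (0 of 25), the proteasome (0 of 32), histones (0 of 4), ergosterol synthesis (0 of 22), mitochondrially encoded genes (0 of 3), MATa-specific genes (0 of 2) and pheromone-induced genes (0 of 4). The Ty element list matched 0 genes of the array annotation.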

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

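The tests on the wild type arrays, the snoRNA test in the strain-by-temperature difference and the tests for added signal on genes above the floor were chosen only after the result was seen. The tRNA, chromosome-end and inside or outside snoRNA lists used in this section were also added after the data were seen.

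EFM5, a lysine methyltransferase gene, and GYP7 were at least 2-fold lower at 37 °C in the mutant and at least 2-fold higher at 37 °C in wild type, with strain-by-temperature differences of -2.34 and -3.72 on the log2 scale. These opposite directions rest on single arrays and the difference was not tested. For EFM5, the wild type difference of 1.01 fell below 2-fold with scaling to a common median (0.67), quantile normalization (0.54), the mean over probe sets (0.49) and an added floor (0.75), and the mutant difference of -1.32 did so with a floor at the 55th percentile (-0.62) and an added floor (-0.87). For GYP7 both stayed past 2-fold under each of these, with -1.36 and 1.48 the smallest.

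Probe sets outside the gene counts also stood out in the mutant at 37 °C. Of 983 measured probe sets with no gene in the annotation, 170 were at least 2-fold higher and 4 lower than on both control arrays, a share of 17.3%, against 2.74% of named genes. Of 266 probe sets with several genes, 11 were higher and 4 lower. A control probe set for the 25S rRNA had a signal of 647 in the mutant at 37 °C against 126, 102 and 100 on the mutant 25 °C, wild type 25 °C and wild type 37 °C arrays, 6.44-fold above the last. Of the other 4 control probe sets for this rRNA, 1 had a signal of 73.0 against 21.4, below the floor, in wild type at 37 °C, at least 3.35-fold, and 3 lay below the floor on all arrays. The control probe sets for the 18S rRNA lay near or below the floor, at most 32.1 on that array.

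The snoRNA and snRNA signal, with a median log2 difference of 1.43 between the strains at 37 °C, could be technical, but scaling does not account for it, since the lowest median over the scaling alternatives was 1.36. Signal added alike to all probe sets, by genomic DNA or background, is argued against by 2476 protein-coding genes with wild type signals between the floor and the median snoRNA gain of 115, whose median was -0.091 (quartiles -0.41 and 0.25) where at least 1 would be needed; the test set beforehand, on dim genes (-0.11), decides nothing because they lie near the floor, and the 190 higher against 13 lower probe sets without a gene at 37 °C go the other way. Less selective priming of poly(A) RNA in the mutant 37 °C sample stays open, because tRNA genes had a median of 0.83, above the bound of 0.71 taken from the snoRNA median. The tRNA list was added after the data were seen. Of its 71 measured genes, 69 had probe sets that can bind further sequences or are incomplete. Against the mutant at 25 °C the tRNA median was 0.63, where the snoRNA and snRNA median was 1.65. In wild type the tRNA median was -0.31 at 37 °C against 25 °C. The first test used lists added after the data were seen. By its bound, it went against the idea that only snoRNAs with their own transcription unit respond. The median of snoRNAs outside protein-coding genes exceeded that of the 4 inside them by 0.28, below the 0.5 set to argue against it. In the strain-by-temperature difference, tried afterwards because the inside snoRNAs already differed at 25 °C, the gap was 1.41. At 25 °C the 4 inside snoRNAs had a median of 1.04 in the mutant against wild type, with 3 past 2-fold. The first test includes this difference, so it does not decide. From 25 °C to 37 °C in the mutant, the inside snoRNAs had a median of 0.28 with 0 of 4 higher. Those outside had 1.67 with 31 of 44 higher. The inside values rest on 4 genes and tRNA genes were higher too. Loss of Nab3 termination is therefore a hypothesis that these arrays do not separate from priming.

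The descriptions of both wild type arrays name the mutant at 25 °C. Against such RNA on the wild type 37 °C array, its general stress genes had a median of 1.44 above the mutant 25 °C array, where a value near 0 would be needed. For mutant RNA from 37 °C on it, the first test left the matter undecided. Of the 73 genes that differed between strains at 25 °C, 72.6% differed the same way at 37 °C, short of the 75% needed. A further test was added after that outcome. It counted 416 genes 2-fold apart between the arrays labelled mutant and wild type at 37 °C, against 73 between the strains at 25 °C. This count does not decide either, because a technical difference of the mutant 37 °C array would also raise it, and the 37 °C arrays have no replicates. Mutant RNA on either wild type array is argued against by the 23 genes above the floor on all arrays and 2-fold apart between the strains at both temperatures, in comparisons that share no array, of which 21 (91.3%, interval 72.0% to 98.9% with genes taken as independent) went the same way where mutant RNA would favour neither direction; a control probe set for URA3 went with the strain labels too, by at least 1.14, although the probe set of the gene itself differed by only 0.24 at 25 °C. A mix-up with a sample outside these 4, or a difference in handling shared by both arrays of a strain, was not tested.

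The PAU and COS genes, with a median of 1.17, could reflect probes shared within the families. Other genes near chromosome ends, a list added after the data were seen, had a median of 0.26. It lay above 100% of the random lists, but between the bounds of 0.25 and 0.58. Shared probes and a wider effect at chromosome ends therefore cannot be told apart from this test. With unique probe sets alone the PAU and COS median was 0.31, and 0.00 in the strain-by-temperature difference, so the value of the group rests on probe sets that can bind several members. Signal added alike to all probe sets is argued against by 2009 protein-coding genes between the floor and the median gain of this list, with a median of -0.093, while the dim genes (-0.11) decide nothing.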

How the results depend on the processing

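The comparison of the mutant at 37 °C with the 25 °C arrays alone was chosen after seeing the data. No paired analysis was possible because there is 1 array per group. No value changed sign while past the threshold, and 71 of the gene counts stayed within 1.5-fold of the reported ones, while 39 moved; for list medians the numbers were 1440 and 16, and for named genes 1767 and 89. Values as deposited, the mean over probe sets and unique probe sets alone moved no gene count. Signals below the floor limit which genes can be counted as changed. Unless stated by construction, the cause was not tested.

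Counts are given as higher and lower genes. The stricter 3-fold threshold gave 70 and 29 genes for mutant against wild type at 37 °C, 295 and 47 for the mutant temperature shift, 146 and 14 for wild type, 9 and 0 for the strains at 25 °C, 74 and 40 for the strain-by-temperature difference, and 48 and 5 against both controls. A common median gave 436 and 460 in the mutant shift, 269 and 242 in wild type, and 84 lower against both controls. Quantile normalization gave 438 and 402, 248 and 136, 29 higher at 25 °C and 100 lower against both controls. A floor at the 55th percentile left 98 lower at 37 °C, 292 higher in wild type, 31 and 12 at 25 °C, 155 lower in the strain-by-temperature difference and 29 lower against both controls. An added floor left 81 lower at 37 °C, 290 higher in wild type, 19 and 5 at 25 °C, 140 and 121 in the strain-by-temperature difference and 17 lower against both controls. A floor at the 25th percentile gave 48 lower at 25 °C. Against the 25 °C arrays alone, which leaves temperature in the comparison, 616 were higher and 134 lower. Of the list medians, 11 of 36 changed sign under a scaling in the mutant shift, 16 of 37 in wild type and 4 of 37 between the strains at 37 °C.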

Other observations

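The tRNA and chromosome-end lists, the list of genes upstream of snoRNAs, the 11 pairs above the floor and the genes named here were chosen after their values were seen.

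tRNA genes were higher in the mutant at 37 °C than in wild type at 37 °C for 31 of 71 measured genes and lower for 0, with a median of 0.83. SUF1 and SUF6 were at least 5.73-fold and at least 5.26-fold higher. The probe sets of 69 of the 71 genes, these 2 included, can bind further sequences or are incomplete by their type, and of the other 2 genes 0 were higher. In wild type, the 63 tRNA genes measured in that comparison had a median of -0.31 at 37 °C against 25 °C. Among protein-coding genes higher than on both control arrays were the hexose transporter gene HXT5 (4.83-fold above wild type at 37 °C), the inositol synthesis gene INO1 (6.79-fold), the thiamine genes THI4 (3.63-fold) and THI20 (3.17-fold), the sulfate permease gene SUL2 (4.62-fold) and the cell wall mannoprotein gene TIR4 (3.77-fold). Among the lower genes were further ribosome assembly genes, NOB1 with a log2 difference of -1.53, LOC1 with -1.40 and SDA1 with -1.35.

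Over 16 pairs of a snoRNA and the gene downstream of it with both measured, the differences at 37 °C correlated with r = -0.53 and a Spearman coefficient of -0.53 across pairs, which are not independent replicates, with bounds entered as values. Over the 11 pairs with all signals above the floor at 37 °C these were -0.40 and -0.47. Where the snoRNA was higher, the gene was higher in 2 of 12 pairs, and otherwise in 2 of 4. SNR47 had a signal of 28.3 in the mutant at 37 °C while YDR042C downstream of it had 532. Genes upstream of snoRNAs on the same strand were higher for 1 and lower for 4 of 25.

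The 8 genes nearest each chromosome end, outside the PAU and COS families, were higher for 12 and lower for 3 of 91 measured genes at 37 °C. YLL066W-B had a signal of 1030 in the mutant at 37 °C against 195 in wild type. FLO1, a flocculin gene, had a signal of 87.7 in the mutant at 37 °C and of 0.60, 0.70 and 0.40 on the other arrays. These other values lie below the floor, so FLO1 was at least 4.02-fold higher, and its probe set is incomplete by its type.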
